A study of Homo sapiens with 4 samples.

How the data were processed

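The samples were 4 sequencing libraries of sgRNA inserts amplified from genomic DNA of sorted DU145 cells, 2 from the flux-up and 2 from the flux-down gate, grouped and numbered by their titles. Per the labels' protocols, genomic DNA was extracted from the collected cells and libraries were made with a commercial NGS preparation kit from Cellecta. The values analysed are the whole-number counts per sgRNA that the authors deposited, not normalized. Per the submitters' processing notes, MAGeCK 0.5.9.5 and the genome build GRCh38 were used. Trimming and mismatch settings are not given in the sources used here. Neither a plasmid pool nor unsorted cells were analysed here, and the fluorescence of the cells was not used here. The sgRNA sequences and their positions were not used here.

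Depth ranged from 16415227 to 21164456 counts per library. The reads are PCR products counted without molecular identifiers. Binomial intervals (exact, 95%) and the limit allowed by a count of 0 (3 counts of the total) therefore cover counting error only. Nothing in the labels says that both replicates came from separate transductions or cultures. The p-values of sgRNAs therefore measure only the spread between these samples, which may be technical. Those of genes compare sgRNA ranks with random ranks, and those of lists compare genes with random lists. Neither of these measures the spread between replicates. Markers of other cell types do not apply, since sgRNAs in genomic DNA were counted.

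All computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures used Python 3.11.15 with matplotlib 3.10.9. An sgRNA was tested with at least 30 counts in at least 2 libraries. This left 3081 sgRNAs, 232 of them controls, and removed 0.0532% of counts. Of the 613 genes, 605 were tested and 36 of these had under 3 sgRNAs. The 8 genes left without a tested sgRNA included 5 on the common-essential list. Each sgRNA was tested with edgeR's quasi-likelihood test (glmQLFit, glmQLFTest), flux-up over flux-down, with TMM scaling, no covariate and Benjamini-Hochberg adjustment. Gene scores followed the robust rank aggregation that MAGeCK uses, re-implemented here. For each gate the sgRNAs were ranked by one-sided p, and the best ranks within the top 0.25 of all sgRNAs gave the score. Its p came from 1000000 simulated sets of as many random ranks, drawn uniformly, so no labels were permuted. MAGeCK itself was not run here. Ratios within replicates 1 or 2 are differences of log2 CPM with TMM scaling and a prior count of 1. The log2 fold change over all 4 libraries was fitted without the replicate number. It is not the average of these ratios, so a gene's or list's value can lie above or below both.

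Gene lists were scored by the mean over members of the gene's median sgRNA log2 fold change against 100000 random lists of as many genes, two-sided, with adjustment over the lists with at least 3 genes tested. The 24 lists tested were PRC2, PRC1 with PR-DUB, COMPASS, SWI/SNF, ISWI, INO80 with SRCAP, NuRD with CHD, HDACs with corepressors, sirtuins, lysine acetyltransferase complexes, bromodomain and YEATS readers, H3K9 methylation with HP1, H3K36, H3K79 and H4K20 methyltransferases, histone lysine demethylases, arginine methyltransferases and deiminases, DNA methylation, histone chaperones, histone kinases and phosphatases, histone ubiquitination, poly(ADP-ribose) polymerases, regulators reported to restrain autophagy, regulators reported to promote it, common-essential chromatin genes and KRAB repression machinery. A list of core autophagy and TOR genes had 0 members among the genes targeted and was not tested. Roles in autophagy and essentiality were assigned from general knowledge. Of the gene symbols, 605 matched the RefSeq gene table of GRCh38.p14, which gave gene coordinates.

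Before the data were examined, the groups, tests, gene lists, the settings to be varied and the rule for naming genes were fixed. The rule takes the 10 genes with the smallest p in each gate, the 2 members with the largest absolute value of each list, any gene past the threshold if they are 30 or fewer, and the members of both autophagy lists, always with at least 3 sgRNAs tested. The value of 1 named gene is not reported here. The other settings tried were other scalings (DESeq2 size factors, total counts, control sgRNAs), other filters (none, 100 counts), other sgRNA tests (DESeq2, limma-voom, a MAGeCK-style negative binomial test), the replicate number as a block, leaving out each library, other gene scores (fry, median, another alpha, without each gene's most extreme sgRNA), an FDR of 0.25, other list tests and square-root CPM for the correlations. Scores by promoter tag, without and with the block, and the search for shared counts within a gene were chosen after seeing the data.

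The workflow was tested on simulated data for the flux-up against flux-down comparison, in 5 runs of 604 genes. Over all runs, 70 genes were changed per fold size. Each had at least 4 sgRNAs tested, all changed alike, so changed genes with fewer or discordant sgRNAs were not simulated. Drawn without structure by replicate number and fitted without a block, 2.86%, 27.1% and 71.4% of genes changed 2-, 4- and 8-fold were recovered, with 0 false calls. Drawn with such structure and fitted without a block, 21.4%, 74.3% and 98.6% were recovered, with 1 false call, and fitted with a block 37.1%, 87.1% and 100% were, with 3 false calls. In the test of lists, on 600 simulated genes, a shifted list gave the smallest p that the random lists allow (1e-05) and 1 of 24 unshifted lists had a p under 0.05.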

Results

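DU145, an established human prostate cancer cell line, carried a tandem reporter in which mCherry and GFP were fused to LC3B, a protein of the autophagosome membrane. GFP loses its fluorescence in the acid lysosome and mCherry keeps it, so the balance of both colours follows autophagic flux, the delivery of autophagosomes to lysosomes. The cells received a CRISPR interference library, in which a nuclease-dead Cas9 is guided to a promoter to lower transcription of the gene. Cells with raised and with lowered flux were then collected by flow sorting, and the question was which epigenetic regulators alter flux when they are repressed. Each gate was represented by 2 libraries of sgRNA counts from genomic DNA. The table held 3590 sgRNAs, of which 3340 targeted 613 genes and 250 were non-targeting controls. Of the genes, 559 had 5 sgRNAs, 53 had 10 and 1 had 15. Total counts were 19370997 and 20550616 in flux-up replicates 1 and 2, and 16415227 and 21164456 in flux-down replicates 1 and 2. In what follows a positive log2 fold change means more counts in the flux-up gate, "replicates 1" and "replicates 2" mean the pair of libraries that share that number, and a gene's value is the median over its sgRNAs with the SD between them.

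The first comparison asked how evenly the library was represented and whether libraries of the same gate resembled each other. An sgRNA against USP22, the ubiquitin-specific protease of the SAGA complex, was the most abundant of flux-up replicate 2, at 4.80% of counts (95% exact interval 4.79 to 4.81), and of flux-down replicate 2, at 5.12% (5.11 to 5.13). The same sgRNA held 0.357% (0.355 to 0.360) of flux-up replicate 1. In flux-down replicate 1 the most abundant sgRNA targeted KAT2B, a lysine acetyltransferase, at 0.675% (0.671 to 0.679). The 100 most abundant sgRNAs took 16.0% and 23.0% of the counts in flux-up and flux-down replicates 1, and 54.7% and 60.8% in flux-up and flux-down replicates 2. The median count per sgRNA was 3051 and 1682 in replicates 1 against 250 and 166 in replicates 2. No count was found for 263 and 282 sgRNAs in flux-up replicates 1 and 2 and for 347 and 115 in flux-down replicates 1 and 2. A count of 0 allowed up to 0.155, 0.146, 0.183 and 0.142 CPM in these 4 libraries.

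**Figure D1:**
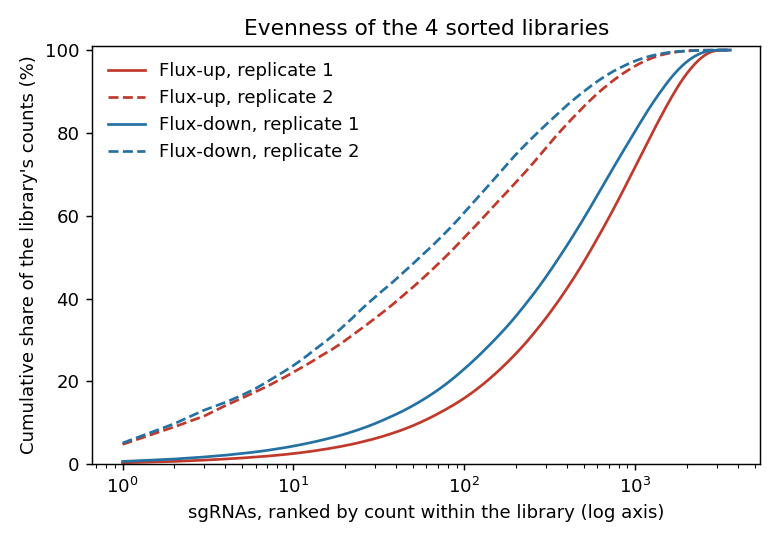
Cumulative share of each library's counts (%, y axis) against sgRNAs ranked by count within the library (x axis, log scale), with 1 line per library. The 100 most abundant sgRNAs hold 16.0% and 23.0% of counts in replicates 1 and 54.7% and 60.8% in replicates 2.

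Across the 3081 sgRNAs tested, which are not independent replicates, log2 CPM (counts scaled to library size) correlated at Pearson's r = 0.784 (Spearman's rho = 0.823) between both flux-up libraries and at 0.801 (rho = 0.875) between both flux-down libraries. The correlation across gates was 0.868 (rho = 0.882) within replicates 1 and 0.917 (rho = 0.929) within replicates 2. The flux-up over flux-down log2 ratio of an sgRNA in replicates 1 correlated with that in replicates 2 at r = 0.0855 (rho = 0.161), that of the control sgRNAs alone at r = 0.353 (rho = 0.240), and that of gene medians at r = 0.113 (rho = 0.145). Among the 605 genes tested, 163 had a median above 0 in both replicates, 174 had a median below 0 in both, 267 had opposite signs and 1, FTSJ3, had 0 in replicates 1.

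Non-targeting control sgRNAs gave the background of the comparison between gates. Their median log2 fold change was -0.00022 with an SD of 1.24 (232 sgRNAs), and that of targeting sgRNAs was 0.20 with an SD of 1.14. The control median was -0.06 (SD 1.21) in replicates 1 and -0.11 (SD 1.46) in replicates 2. No control passed the edgeR test and 3 had an unadjusted p under 0.05. Of 46 sets of 5 controls scored as if each were a gene, 1 had an unadjusted p under 0.05 for the flux-up gate, 1 for the flux-down gate, and 0 passed after adjustment. The median over all sgRNAs tested depended on the scaling, at 0.19 with TMM, 0.018 with DESeq2 size factors, 0.51 with total counts and 0.07 with control sgRNAs. The control median was -0.00022, -0.13, 0.35 and -0.10 in the same order.

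The main comparison asked which repressed genes were more frequent in either gate. MED24, a subunit of the Mediator complex that links transcription factors to RNA polymerase II, ranked first for the flux-up gate, with a median log2 fold change of 3.17 (SD 1.53, 5 sgRNAs). Its adjusted p was 0.0508 in the rank aggregation test against random ranks, so it did not pass. The MED24 median was 4.33 in replicates 1, where 5 of 5 sgRNAs were above 0, and -0.91 in replicates 2, where 1 of 5 was. In flux-down replicate 1, 3 of the 5 MED24 sgRNAs had the identical count of 32, which was 2 above the filter, and 6 targeting sgRNAs of that library had this count, these 3 included. No other gene of that library, and no gene of the other libraries, had 3 sgRNAs with the same count of 10 or more. With at least 100 counts required in 2 libraries, the MED24 median was 0.83 and its adjusted p 0.935.

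The other genes ranked among the first 10 for the flux-up gate each had an adjusted p of 0.360. BRD9, a bromodomain subunit of the non-canonical BAF remodelling complex, had a median of 1.54 (SD 1.06, 4 of 4 sgRNAs above 0), with 1.60 in replicates 1 and 1.46 in replicates 2. CARNMT1, a carnosine methyltransferase, had 1.55 (SD 0.98, 5 of 5 above 0), with 1.65 and 0.97. PHF12, a PHD finger protein of SIN3 complexes, had 1.66 (SD 2.04, 3 of 4 above 0), with 1.77 and 0.84. SGF29, the Tudor-domain reader of SAGA, had 1.58 (SD 0.99, 3 of 4), with 0.74 and 1.84, and TRIM33 had 1.22 (SD 0.86, 4 of 4), with 1.61 and 0.91. WDR82, a subunit of SETD1 methyltransferase complexes, had 1.48 (1.70 and 0.18), and ARID1B, a subunit of canonical BAF, had 1.29 (0.23 and 1.66). METTL17 had 1.33, with 1.56 in replicates 1 and -0.31 in replicates 2. MPHOSPH8, the H3K9 methylation reader of the HUSH silencing complex, had 0.37 (SD 1.07, 9 sgRNAs), with 0.56 and 0.21. Its 5 sgRNAs tagged P1, read here as a promoter tag, had a median of 1.54 and the 4 tagged P2 had -0.11.

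Genes ranked first for the flux-down gate each had an adjusted p of 0.730. SMARCC1, a core scaffold of the BAF complexes, had a median of -1.57 (SD 1.51, 0 of 4 sgRNAs above 0), with -1.34 in replicates 1 and -2.11 in replicates 2. MGA, a MAX-binding repressor of the non-canonical PRC1.6 complex, had -1.47 (SD 1.76, 4 sgRNAs), with -0.77 and -3.51. MBD5, a methyl-CpG-binding domain protein, had -1.81 (SD 0.69, 3 sgRNAs), with -1.01 and -2.23. TRIM28, the corepressor of KRAB zinc finger proteins, had -1.16 (SD 0.82, 3 sgRNAs), with -1.46 and -0.38. DPY30, a core subunit of COMPASS methyltransferases, had -1.31, with -1.43 in replicates 1 and -0.00093 in replicates 2. JMJD8 had -0.73, PAGR1 -0.90, JADE3 -0.83, MIER1 -0.92 and PARP14 -0.17.

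No sgRNA and no gene passed an FDR of 0.05 in the edgeR fit, which does not model the replicate number although libraries correlated more by number than by gate, as given above. Unadjusted p-values under 0.05 were found for 38 sgRNAs (9 higher in flux-up, 29 higher in flux-down) where 154 would be found by chance, and for 41 genes in the flux-up and 35 in the flux-down direction where 30.25 would be found by chance in each. The DESeq2 Wald test called 0 sgRNAs, limma-voom 1 and a MAGeCK-style negative binomial test 143, and each of the 3 called 0 genes in either direction. These 3 tests did not model the replicate number either. The median standard error of an sgRNA's log2 fold change was 1.55 and the coefficient of variation between libraries of a gate was 96.7%. Both include the difference between replicate numbers, so the low count of sgRNAs cannot show that signal is absent. The MED24 median was -0.62 without flux-up replicate 1 (adjusted p 0.978), 4.12 without flux-up replicate 2 (0.0127), 0.60 without flux-down replicate 1 (1) and 3.44 without flux-down replicate 2 (0.154).

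**Figure D2:**
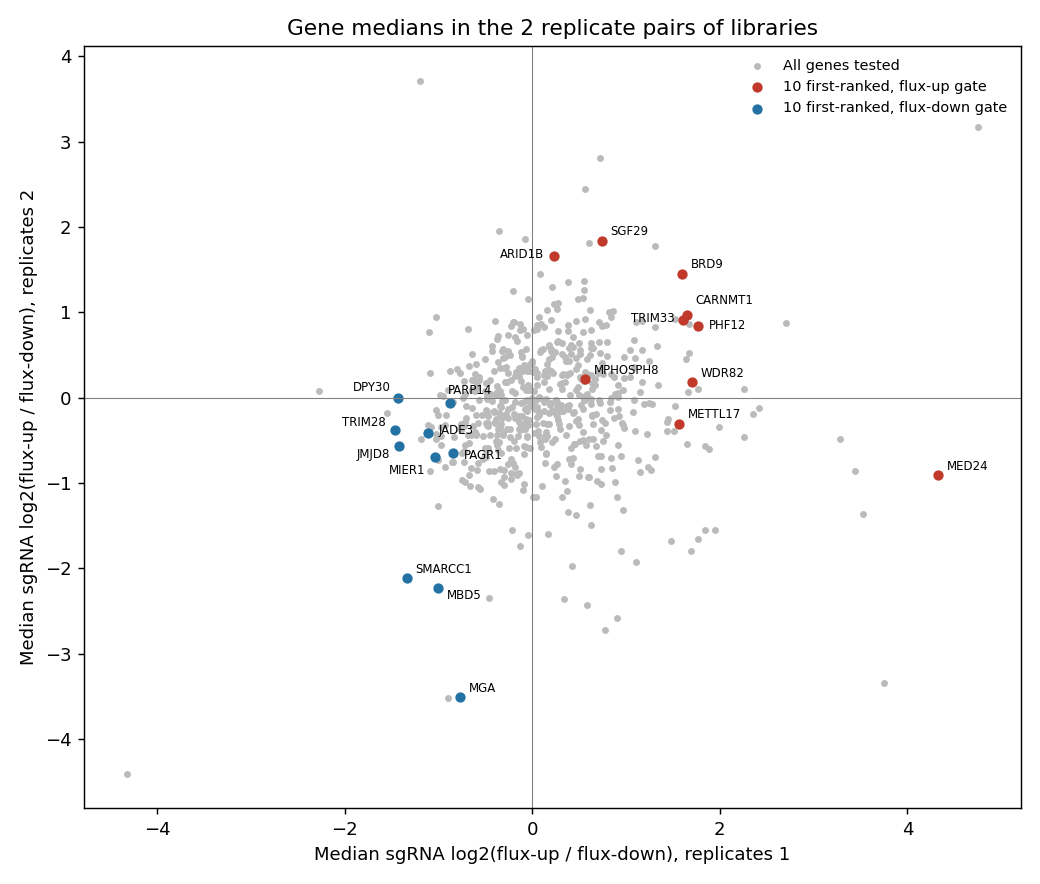
Median sgRNA log2 ratio of flux-up over flux-down counts per gene in replicates 1 (x axis) and replicates 2 (y axis), 1 point per gene tested, with the 10 first-ranked genes of each gate coloured and named. MED24 lies at 4.33 and -0.91, BRD9 at 1.60 and 1.46, and SMARCC1 at -1.34 and -2.11.

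**Figure D3:**
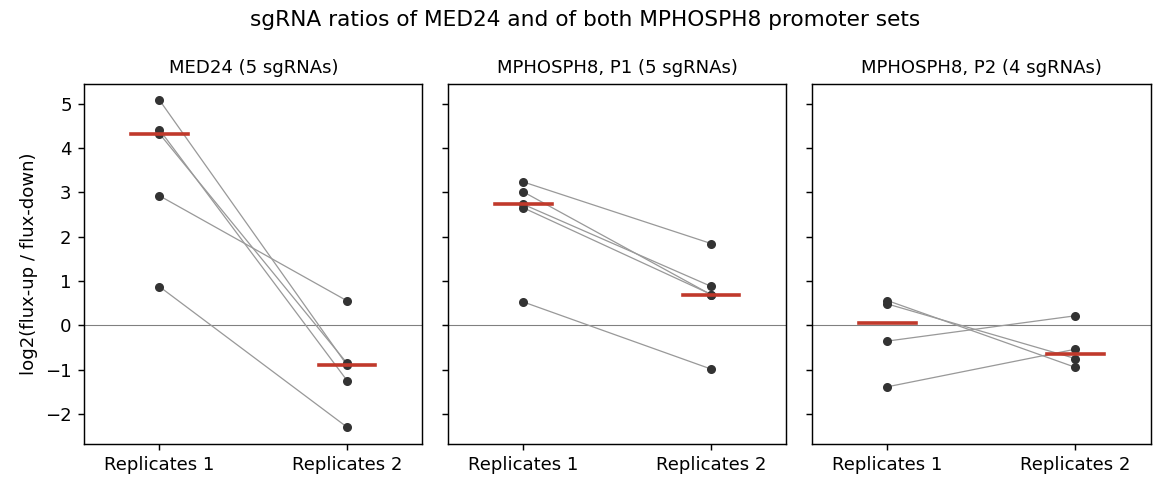
Log2 ratio of flux-up over flux-down counts (y axis) of each sgRNA of MED24 and of MPHOSPH8, by promoter tag, in replicates 1 and 2 (x axis). Grey lines join the values of an sgRNA and red bars mark medians, at 4.33 and -0.91 for MED24, 2.73 and 0.70 for MPHOSPH8 P1, and 0.06 and -0.65 for MPHOSPH8 P2.

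Among MED24, MPHOSPH8 and SMARCC1, the RefSeq annotation of GRCh38.p14 places MED24 on chromosome 17 (40019104 to 40054408), MPHOSPH8 on chromosome 13 (19633659 to 19673441) and SMARCC1 on chromosome 3 (47585269 to 47781893). BRD9 spans 863741 to 892801 on chromosome 5 and MGA spans 41621224 to 41769940 on chromosome 15. These are spans of genes, and the positions of the sgRNAs were not used here.

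Chromatin regulators with a reported role in autophagy were compared with the other genes of the library. The regulators reported to restrain autophagy had a mean gene median of 0.63, against 0.21 over all genes (permutation p = 0.0704, adjusted p = 0.665, permutation of gene lists). In this list 7 of 8 genes were above 0, against 391 of 605 among all genes tested. The list's mean was 0.55 in replicates 1 and 0.35 in replicates 2, where the median ratio over all sgRNAs tested was 0.052 and -0.067. Its members included EHMT2, an H3K9 methyltransferase, at 1.31 (1.31 and 0.83 in replicates 1 and 2), CREBBP at 0.72 (0.47 and 0.90), EZH2 at 0.51 (0.57 and -0.03) and EP300 at -0.025 (0.29 and -0.37). KDM1A had 0.57 (1.17 and 0.89), HDAC1 0.39 (0.053 and 0.15) and HDAC2 0.77 (0.12 and -0.30). The regulators reported to promote autophagy had a mean of 0.15, with 5 of 8 above 0 (permutation p = 0.799), and means of 0.096 and 0.042 in replicates 1 and 2. In that list SIRT1, an NAD-dependent deacetylase, had -0.81 (-0.14 and -0.89), HDAC10 had -0.52, PRKAA1, a catalytic subunit of AMPK, had 0.80 (0.67 and 0.22), and CARM1 had 0.77 (0.91 and 0.011). SIRT6 had 0.46 (0.51 and -0.84), PARP1 0.48 (-0.073 and 1.87), HDAC6 0.15 (-0.73 and 0.19) and PRKAA2 -0.11 (-0.14 and 0.35). No member of either list passed when adjusted over the list alone. The mean of the list reported to restrain autophagy was -0.13 without flux-up replicate 1, 0.069 without the count filter and 1.05 with total counts, where the median over all sgRNAs was 0.51. A camera test of this list gave an unadjusted p of 0.0467 with a preset correlation and 0.269 with an estimated one.

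Complexes and enzyme families were compared in the same way, and 0 of 24 lists passed (smallest adjusted p 0.665). INO80 and SRCAP, remodellers that exchange the histone variant H2A.Z, had the only unadjusted p under 0.05, with a mean of 0.65 and 7 of 9 above 0 (permutation p = 0.0497), and means of 1.03 in replicates 1 and -0.47 in replicates 2. The mean was -1.05 without flux-up replicate 1 (permutation p = 0.0916), 0.23 without the count filter (0.827), 0.29 at 100 counts (0.779), 0.40 with DESeq2 size factors (0.0808), 1.07 without flux-down replicate 1 (0.246), 1.12 without flux-up replicate 2 (0.00747) and 1.26 with total counts (0.0114). Across all sgRNAs, abundance in replicates 2 correlated with the ratio in replicates 1 at r = -0.458, abundance in replicates 1 with the ratio in replicates 2 at r = 0.147, and the abundance of this list was low, as given in the closing part. Its members ACTR8 and ACTR6, actin-related subunits, had 2.38 (3.28 and -0.48) and 1.87 (2.42 and -0.12). Histone chaperones had 0.65 (permutation p = 0.163, 2 of 4 above 0), with 0.77 in replicates 1 and -0.24 in replicates 2, and DAXX had 1.08 (1.09 and -0.021). SWI/SNF subunits had -0.0025 (permutation p = 0.146, 11 of 20 above 0), with SMARCC1 and BRD9 on opposite sides of 0 as given above. DNA methylation proteins had -0.06 (permutation p = 0.0888, 10 of 17 above 0), with MBD5 as given above and DNMT3L at 1.07. Arginine methyltransferases and deiminases had -0.06 (permutation p = 0.166), with PADI4 at -0.82, and sirtuins -0.04 (permutation p = 0.289), with SIRT7 at -0.84. Bromodomain and YEATS readers had 0.39 (permutation p = 0.198), with 0.34 in replicates 1 and -0.16 in replicates 2, and TAF3 had 1.19 (1.04 and 0.24). The machinery of KRAB repression had 0.39 (permutation p = 0.339), with 0.38 in replicates 1 and -0.13 in replicates 2. Its members SETDB1 and CHD4 had 1.76 (3.45 and -0.86) and 1.73 (1.84 and -0.56).

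PRC2 had a mean of 0.38 (permutation p = 0.435), with 0.32 in replicates 1 and -0.056 in replicates 2. Its members PHF19 and JARID2 had 0.91 (0.41 and -0.78) and 0.73 (0.38 and 1.36). PRC1 with PR-DUB had 0.18 (permutation p = 0.795), with -0.13 in replicates 1 and 0.054 in replicates 2. BAP1 had 0.79 (0.98 and 0.48) and PCGF5 0.71 (0.18 and 0.32). COMPASS subunits had 0.092 (permutation p = 0.486), with CXXC1 at 1.49 (1.31 and 1.78). ISWI had 0.22 (permutation p = 0.975), with 0.15 in replicates 1 and -0.20 in replicates 2. BPTF had 0.73 (0.92 and -0.56) and RSF1 0.60 (0.37 and 0.26). NuRD and CHD proteins had 0.35 (permutation p = 0.403), with 0.19 in replicates 1 and -0.16 in replicates 2, and CHD1 had 1.08 (1.14 and 0.063). HDACs with their corepressors had 0.25 (permutation p = 0.764), with 0.24 in replicates 1 and -0.16 in replicates 2, and HDAC11 had 1.24 (1.35 and 0.15). Lysine acetyltransferase complexes had 0.26 (permutation p = 0.627), with ING3 at 1.35, and H3K9 methylation with HP1 0.23 (permutation p = 0.881), with SETDB1 and EHMT2 as above. Methyltransferases of H3K36, H3K79 and H4K20 had 0.24 (permutation p = 0.880), with 0.39 in replicates 1 and -0.20 in replicates 2. DOT1L had 0.93 (2.71 and 0.87) and NSD2 -0.90 (0.34 and -2.36). Histone lysine demethylases had 0.17 (permutation p = 0.768), with 0.10 in replicates 1 and -0.067 in replicates 2. KDM6B had 1.38 (1.53 and 0.93) and KDM8 1.28 (1.28 and -0.071). Histone kinases and phosphatases had 0.34 (permutation p = 0.596), with 0.53 in replicates 1 and -0.29 in replicates 2, and EYA2 had 0.99 (1.84 and -1.55). Histone ubiquitination enzymes had 0.18 (permutation p = 0.844), with USP21 at 1.20 (-1.20 and 3.72). Poly(ADP-ribose) polymerases had 0.21 (permutation p = 0.999), with PARP2 at 1.58 (1.67 and 0.53) and PARP8 at 1.31 (1.43 and -0.39). Common-essential chromatin genes had 0.33 (permutation p = 0.264), with means of 0.45 in replicates 1 and -0.43 in replicates 2. Adjusted over the list alone, MPHOSPH8 passed in the H3K9 list (0.0456) and in the KRAB list (0.0335), and no other member of the 24 lists did. Both rest on the same rank aggregation p of MPHOSPH8, whose adjusted p over all genes was 0.360. Adjustment within a list does not account for the 24 lists or for both directions. A camera test on sgRNAs, with a preset or an estimated correlation, and fry called 0 lists.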

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

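Scores by promoter tag, without and with a replicate block, were chosen after seeing the data, and the other alternatives were planned. In the flux-up direction, where 0 genes passed, 1 gene (MED24) passed with DESeq2 size factors (adjusted p 0.0424), with control-sgRNA scaling (0.0393), with the median as gene score, without each gene's most extreme sgRNA (0.0381) and at an FDR of 0.25. With total-count scaling 2 passed (MED24 at 0.0248 and MPHOSPH8 at 0.0121). Over the settings of scaling, filter, sgRNA test, block and left-out library, the adjusted p of MED24 ranged from 0.0127 to 1. In the flux-down direction 1 gene passed without a count filter (BRCA1, 0.0497, named after its value was seen), and its sgRNAs are those the filter removes. For sgRNAs, limma-voom called 1 (against DIDO1, 0.0253, named after its value was seen) and the MAGeCK-style test 143 (136 higher in flux-up, 7 higher in flux-down, 8 of them controls). Gene lists past the threshold were 0 under every alternative run. Leaving out 1 library, which leaves its gate with 1 sample assumed to vary like the other gate, gave 0 to 1 genes for flux-up (MED24 without flux-up replicate 2), 0 for flux-down, 0 sgRNAs, 0 lists and a control median between -0.11 and 0.22. Of 819 values of the 63 named genes under the alternatives, 58 had the opposite sign without a call, 26 of these without flux-up replicate 1, 1 had it with a call, and 44 of the 63 genes had it, called or not, under at least 1 alternative. The mean correlation within a gate moved from 0.792 to 0.823 without a filter, 0.818 at 100 counts and 0.722 on square-root counts, that within a replicate number from 0.892 to 0.913 without a filter, and that of gate ratios from 0.0855 to 0.0163, 0.216 and 0.549. For these changes the cause was not tested. In simulated data fitted without a block, 2-fold changes were recovered for 2.86% of genes without structure by replicate number. With such structure, which these libraries had, 21.4% were recovered.

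With the replicate number as a block, 89 sgRNAs (18 higher in flux-up, 71 higher in flux-down, 9 of them controls, or 3.88% of controls against 2.81% of targeting sgRNAs, Fisher's exact p = 0.311) and 1 gene for flux-up passed, MPHOSPH8 (0.00968), whose median was then -0.0713. The score counts a gene's best-ranked sgRNAs, so it can pass with a median below 0. Unadjusted p-values under 0.05 were found for 378 sgRNAs against 38 without the block, and the median standard error was 0.709 against 1.55. Of the lists, 0 passed, with 0.53 for regulators reported to restrain autophagy (unadjusted permutation p = 0.0319) and 0.22 for INO80 with SRCAP (0.389). In simulated data with structure by replicate number, 2-fold changes were recovered for 21.4% of genes without and 37.1% with the block, with 1 and 3 false genes. By promoter tag with the block 1 set passed, MPHOSPH8 P1. The labels give shared numbers only, and 2 of them, so the numbers were not taken as pairs, although libraries of the same number deviated together from the gate means (r = 0.669, rho = 0.703).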

Other observations

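The tests in this part were chosen after the result was seen, except the test of sibling sgRNAs, and the genes named for abundance alone were chosen after their values were seen. The abundance of targeting sgRNAs over all 4 libraries, relative to the non-targeting controls, differed between gene groups, and 4 lists passed. Counts under 3 in a library were set to 3 for these values, so the medians of 53 genes are upper bounds, and means that hold such genes are too. The mean of gene medians was -1.42 on the log2 scale. Common-essential chromatin genes had a mean of -4.62 (SD 3.30, 38 genes, 16 at a bound, adjusted p = 0.00024, permutation of gene lists). INO80 and SRCAP subunits had -4.27 (10 genes, 2 at a bound, adjusted p = 0.0115) and histone chaperones -6.54 (3 of 4 at a bound, permutation, adjusted p = 0.0054). Both lists share genes with the common-essential list, so these are not separate results. Shared were INO80, ACTR6, ACTR8, RUVBL1 and RUVBL2, and CHAF1A and CHAF1B of the chaperones. PRC1 with PR-DUB had 0.16 (23 genes, 0 at a bound, adjusted p = 0.0271), with 0.018 and 0.47 in flux-up replicates 1 and 2 and -0.13 and 0.43 in flux-down replicates 1 and 2. Without flux-up replicate 2 it had 0.093 and did not pass (adjusted p = 0.0562), while the other 3 lists passed without any 1 library. The AAA+ ATPases RUVBL1 and RUVBL2, the maintenance DNA methyltransferase DNMT1 and WDR5 had a median sgRNA with 3 counts or fewer in every library, which gives -8.80 as a bound for each. Neither a plasmid pool nor unsorted cells were analysed here, so these are levels and not changes.

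For the 49 genes with separate P1 and P2 sgRNAs, the mean gap between the medians of both sets was 3.03. It was 2.57 with tags shuffled within genes (permutation p = 0.0164). Taken alone, 0 genes passed, but the 10 sgRNAs of a gene allow few distinct splits of the tags. The smallest unadjusted permutation p of any gene was 0.0466 (HR). Adjusted over 49 genes such values could hardly pass, so the single-gene result does not count against a gap. The widest gaps were those of KAT8, the acetyltransferase of H4K16, with an upper bound of -8.80 for P1 against 1.57 for P2 (adjusted p = 0.352), of PRMT5, with -7.75 as a bound against 1.46 (0.352), and of DPF2, with -7.05 as a bound against 1.38 (0.352). The order was the opposite for HR, at 1.76 for P1 and a bound of -6.66 for P2 (0.352). PKM had -5.38 and 1.43 (0.639).

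The libraries grouped by replicate number rather than by gate, and the 100 most abundant sgRNAs held 54.7% and 60.8% of the counts of replicates 2. A split by replicate number gave 1086 sgRNAs past the threshold, against 0 for the split by gate and 0 for the crossed split, while genes past the threshold were 0, 0 and 2. Lower depth is argued against by total counts 1.17 times higher in replicates 2. PCR jackpots that arose in each library separately, as the whole cause, are argued against by shared sgRNAs. The 100 that gained most from replicates 1 to replicates 2 in each gate shared 50 (3.25 by chance). For a growth advantage set by the targeted gene, 52.6% of 344 sibling sgRNAs lay above the median gain (exact interval 47.2 to 58.0). Siblings were taken as independent and the 100 that gained most were left out, which lowers the share, so such an advantage stays open. The 100 most abundant sgRNAs shared 69 between both libraries of replicates 2, 54 between those of replicates 1, 36 between both flux-up and 49 between both flux-down libraries. A small founding population of cells shared by both gates stays open, as does any other event before sorting, since the correlation of the gain between gates (0.669) restates the grouping and cannot tell them apart.

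MED24 ranked first for the flux-up gate through replicates 1. Its median was -0.91 in replicates 2, so an effect of the libraries of replicates 1 alone may account for the rank. Its abundance was low, at -4.25 against the controls. Across all sgRNAs, lower abundance in replicates 2 went with a higher ratio in replicates 1 (r = -0.458). Of the 5 MED24 sgRNAs, 3 had an identical count of 32 in flux-down replicate 1. With gene names shuffled, a mean of 0.001 genes of that library had 3 sgRNAs sharing a count of 10 or more (permutation p = 0.0011). That search was formed after these counts were seen, so it cannot exclude chance. Whether the shared count comes from chance, from the cells or from how the reads were counted stays open. Mediator genes as a group, a list formed after MED24 was seen, had a mean of 0.42 (25 of 32 genes above 0, against 391 of 605 in the library, permutation p = 0.0742), and without MED24 0.33 (24 of 31 above 0, permutation p = 0.306), with 0.42 in replicates 1 and -0.25 in replicates 2.

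The P1 sgRNAs of MPHOSPH8 were more frequent in the flux-up gate. An effect of replicates 1 alone stays open, since the median was 0.70 in replicates 2 (range -0.99 to 1.85) after 2.73 in replicates 1, with 4 of 5 sgRNAs above 0 in both, in a set picked partly on replicates 2. Chance among the 682 sets formed by name tag stays open. The adjusted p of the rank aggregation test was 0.000682 with the replicate block and 0.0968 without it, and the P1 set was picked for its rank. The 682 sets include whole genes tagged P1P2 and single sgRNAs of CDY genes, whose names hold no such tag. A hypothesis is that loss of HUSH-linked H3K9 repression moves cells to the flux-up gate. The mean of its partners SETDB1 and ATF7IP lay at percentile 99.5 of all gene pairs in replicates 1 and at 49.3 in replicates 2, so that test did not decide it. The abundance of SETDB1 was low, at -3.98 against the controls, and that of ATF7IP was 0.34. Across all sgRNAs, lower abundance in replicates 2 went with a higher ratio in replicates 1 (r = -0.458). TRIM28, on the same H3K9 list, had -1.46 in replicates 1 and -0.38 in replicates 2.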
